A study of Mus musculus with 15 samples.

How the data were processed

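The series is a chromatin immunoprecipitation sequencing (ChIP-seq) study of p53, the transcription factor encoded by Trp53, in organs of wild-type mice. ChIP-seq sequences the DNA fragments that an antibody pulls down with a protein. The labels describe 15 libraries. Liver, spleen and thymus each have 5: 2 from untreated mice, 2 taken 3 h after 2 Gy of X-rays, and 1 input library, which is chromatin sequenced without the antibody step. The title of the series names p53 as the target. The antibody itself is not named in the labels.

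The authors deposited 3 headerless lists of genomic regions, 1 per organ, each with 6 columns. The score of each region is the authors' own value and its scale is not given in the sources used here. Per the labels, the same list belongs to all 5 libraries of an organ, the untreated and input libraries included. The name of each list refers to irradiation and to IgG (a nonspecific antibody control), although none of the libraries is labelled IgG. The lists are therefore described as organ lists, and whether libraries were pooled or subtracted before the regions were called is not given. Genome build mm10 is named in the submitters' processing notes. The region caller, its settings and the aligner are not given in the sources used here.

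Each list is a single measurement per organ. No values per library were analysed here, so the effect of radiation, the spread between replicates and the background in the input libraries could not be tested, and read depth is unknown. Tests below treat regions or genes as units. They describe these lists and say nothing about how another set of mice would vary. Confidence intervals are exact Clopper-Pearson 95% intervals unless named otherwise and cover counting error only.

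Region boundaries lie on multiples of 50 bp. Across the 3 lists there were 4137 distinct regions and 0 that overlapped another only in part, with a smallest gap of 350 bp. The lists are thus subsets of a common set of regions, which raises their overlap by construction. Overlap meant at least 1 bp shared. It was compared with 1000 random placements of the smaller list within its chromosomes, with widths kept; these placements were not matched to open chromatin, and the common set fixes their outcome for overlaps. Shares were therefore also set beside those that random draws of the same sizes from the distinct regions would give, a comparison added after the data were seen. Chromosome lengths were approximated by the last gene or region end. Scores were used only as rank percentiles within a list, with ties averaged, and shared regions were compared with those of a single list by a two-sided permutation test of medians with 100000 resamples. Across regions that a pair of lists shared, score ranks were compared by Spearman's rho with 1000 bootstrap draws for its interval; regions are not independent replicates.

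Genes came from the RefSeq annotation of GRCm38.p6, the assembly that mm10 names, with 49943 genes of any kind on the autosomes and sex chromosomes, 21887 of them protein-coding. The table used here has gene starts and ends without strand or exons, and no genome sequence was used here. The planned transcription start site therefore became either end of a gene, the planned 5 kb upstream window became 5 kb on both sides of a gene, exons, introns and untranslated regions were not told apart, and the planned search for p53 response elements was not run. A region was placed at a gene end when its midpoint lay within 1 kb of either end of any annotated gene. Shares were compared with the random placements, and between lists or classes of regions by two-sided Fisher's exact tests. Regions that a pair of lists shares count on both sides of the tests between lists, so these were repeated on regions that only 1 list of the pair holds.

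Before the data were examined, 16 gene lists were fixed: 5 of p53 target genes (feedback and p53 regulation, cell cycle, apoptosis, DNA repair, and metabolism and redox), markers of hepatocytes, liver lipid and bile acid metabolism, T cells, B cells, myeloid and erythroid cells, and endothelial, stromal and epithelial cells, NF-kB and interferon genes, immediate early genes, circadian genes, and housekeeping and neuronal controls. Of 394 entries, 392 matched a coding gene, 3 of them through a synonym. A few genes sit in more than 1 list, such as Btg2. For each list, the number of genes with a region inside the gene or within 5 kb of it was compared with 10000 random lists matched on gene length decile, a permutation test of list membership. Intervals of the ratio to the random mean scale the exact interval of the share and leave the random mean fixed. Two-sided p-values were adjusted by Benjamini-Hochberg over the 48 combinations of list and organ, with a threshold of 0.05. The smallest p that random lists can give is 0.0002 and that of the placements is 0.002. Differences between organs used exact McNemar tests over list members, 51 in all with the combined p53 list included.

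Named genes followed rules fixed in advance: up to 20 p53 list genes with a region in all 3 lists by summed score rank; the nearest coding gene within 50 kb of the 10 highest-scoring regions of each list; the same for the highest-scoring regions over 10 kb from both other lists; and up to 4 members of every other list by score. Tied scores were ordered by width and then position. Genes named outside these rules are said to be so, and 1 myeloid and erythroid list member that the rules select is not reported here.

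The procedures were tested on simulated data. In a simulated liver and thymus overlap, 400 of 400 planted shared regions were recovered. The planted regions were copies of liver regions and the others were chosen to miss the liver list, so this outcome was fixed. For the gene list test in liver over 21887 genes, 1.5% of 200 lists of 20 genes drawn at the matched rate were called, against 85.5% of lists drawn at 3 times that rate. Alternatives fixed in advance were reciprocal overlap of 50%, midpoints within 500 bp, the upper 50% of each list by score, lists shortened to the size of the shortest, autosomes alone, local moves of 50 to 500 kb as the random model, region width in place of score, gene-end distances of 5 kb, coding genes alone, gene windows of 1 kb or 10 kb around gene ends, and no matching on gene length. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.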

Results

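The deposited lists record where p53 ChIP-seq signal was called in liver, spleen and thymus of wild-type mice. Liver, which survives irradiation comparatively well, was set beside spleen and thymus, a pair of lymphoid organs whose cells die readily after it. The series title places liver-specific gene regulation by p53 at the centre of the study. The liver list held 3872 regions, the spleen list 2604 and the thymus list 2405. Median widths were 150 bp in liver and 250 bp in spleen and thymus, and the summed widths were 838800, 623200 and 581150 bp. The lowest score was 7.0 in each list, and the highest was 51.8 in liver, 35.0 in spleen and 30.7 in thymus. With 1 list per organ there are no replicates, and differences in list length cannot be separated from differences in read depth, which is unknown.

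Known p53 target genes carried regions in every organ. Of the 85 genes in the 5 p53 lists combined, 49 had a region in liver, 45 in spleen and 39 in thymus, against means of 13.9, 7.34 and 6.41 in random length-matched lists. These are 3.53, 6.13 and 6.09 times the random means (permutation p = 0.0002 in each organ, the smallest that 10000 random lists can give). A region in all 3 lists was found for 38 of the genes, 7 had regions in exactly 2 lists, 5 in liver alone and 35 in none. The 5 with a region in liver alone were Aldh4a1, Gdf15, Rev3l, Sesn1 and Fancc, named here after their values were seen.

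Of the 5 p53 lists, those of p53 regulation and of the cell cycle had the largest shares of genes with a region. In the feedback list, 10 of 13 genes had a region in liver, 10 in spleen and 8 in thymus (random means 2.38, 1.25 and 1.11; adjusted permutation p = 0.00107 in each). Mdm4, an inhibitor of p53, had a region inside the gene on chromosome 1 (133020101 to 133020650, mm10) that ranked at the 88.1 percentile of scores in liver, 95.4 in spleen and 98.5 in thymus. Ccng1, which encodes cyclin G, had one on chromosome 11 (40754801 to 40755850) at percentiles of 99.6, 87.3 and 88.9. Trp53inp1, a stress-induced partner of p53, had its best region across the gene end in liver (chromosome 4, 11155801 to 11156650; percentile 99.9). In spleen and thymus its best region lay 1522 bp outside the gene (11175901 to 11176650; percentiles 92.4 and 89.0); both regions were in all 3 lists. Aen, a nuclease gene of the same list, ranked at 97.8 in liver, 89.0 in spleen and 55.4 in thymus (chromosome 7, 78895701 to 78896350). In the cell cycle list, 9 of 13 genes had a region in each organ (random means 1.57, 0.780 and 0.672; adjusted permutation p = 0.00107). The region at Cdkn1a, the cyclin-dependent kinase inhibitor gene, spanned 29090601 to 29091250 on chromosome 17 and ranked at 99.04, 95.4 and 98.9. Phlda3, which encodes a repressor of Akt signalling, had a region at a gene end (chromosome 1, 135765801 to 135766650) at 99.3, 97.6 and 98.4.

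The pair of targets with the highest summed score ranks, Zmat3 and Bbc3, belonged to the apoptosis list. It had 11 of 18 genes with a region in liver, 11 in spleen and 10 in thymus (random means 2.82, 1.39 and 1.19; adjusted permutation p = 0.00107). The BH3-only gene Bbc3 (Puma) had a region of 2050 bp at a gene end (chromosome 7, 16308301 to 16310350), with the joint highest score in both liver and thymus and a percentile of 98.5 in spleen. Zmat3, an RNA-binding zinc finger gene, had a region inside the gene (chromosome 3, 32364101 to 32364550) at percentiles of 99.8, 99.6 and 99.8. Bax, the mitochondrial effector of apoptosis, ranked at 99.9 in liver, 97.6 in spleen and 95.3 in thymus (chromosome 7, 45466201 to 45466950). The death receptor gene Fas ranked at 65.6 and 57.3 in liver and spleen and at 86.8 in thymus (chromosome 19, 34292201 to 34292550). Pmaip1 (Noxa) had its best region across the gene end in liver (chromosome 18, 66458301 to 66458650; percentile 76.6) and 4343 bp outside it in spleen and thymus (66469901 to 66470150; 99.6 and 86.8).

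The metabolism and redox list also counts Notch1, Epha2 and Cd80, so it is not made of metabolic and redox genes alone. A smaller share of the genes of that list had a region. A region was found for 12 of 27 such genes in liver, 9 in spleen and 8 in thymus (random means 4.31, 2.25 and 1.97; adjusted permutation p = 0.0056, 0.00192 and 0.00436). Dyrk3, a protein kinase gene, had a region of 1850 bp (chromosome 1, 131138201 to 131140050) at percentiles of 99.8, 98.1 and 96.3. Ddit4, an inhibitor of mTORC1 signalling, had one 1025 bp outside the gene at 82.6, 80.0 and 79.3 (chromosome 10, 59948301 to 59948650). The region nearest Notch1 lay 2879 bp outside that gene (chromosome 2, 26506701 to 26507250) at 94.4, 89.0 and 99.4; Notch1 also acts in T-cell development. The receptor kinase gene Epha2 held a region at 94.3, 97.6 and 76.0 (chromosome 4, 141304101 to 141304550). DNA repair genes passed the threshold of the permutation test in spleen (6 of 14, random mean 1.65, adjusted p = 0.0266) and missed it in liver (7 of 14, random mean 2.77, adjusted p = 0.0691) and thymus (4 of 14, random mean 1.501, adjusted p = 0.241). The liver and spleen counts include Ddit4l, a relative of Ddit4, so they are not of repair genes alone. The spleen ratio to the random mean was 3.63 (1.496 to 6.02). The spleen call was lost with windows of 1 kb around gene ends (3 genes, ratio 6.75, 1.47 to 16.0, adjusted permutation p = 0.0665), with windows of 10 kb (4 genes, 3.27, 0.961 to 6.66, adjusted p = 0.153) and in the upper 50% of regions by score (3 genes, 4.16, 0.904 to 9.86, adjusted p = 0.206). It was also lost in regions away from gene ends and in regions of all 3 lists (3 genes each; ratios 2.74 and 2.54; adjusted permutation p = 0.429 and 0.508), settings chosen after the data were seen. The intervals were wider in these settings, where the random means were smaller (0.445 to 1.22, against 1.65), and all include 3.63. Without matching on gene length the liver count passed (7 genes, random mean 2.14, adjusted permutation p = 0.0151). Mgmt, which repairs alkylated guanine, had a region in all 3 lists (chromosome 7, 136894701 to 136895050; percentiles 70.5, 71.9 and 64.5). The other named targets, Psrc1, Rps27l, Ei24 and Ckap2, had percentiles between 58.2 (Ckap2 in spleen) and 99.5 (Rps27l in liver).

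**Figure D1:**
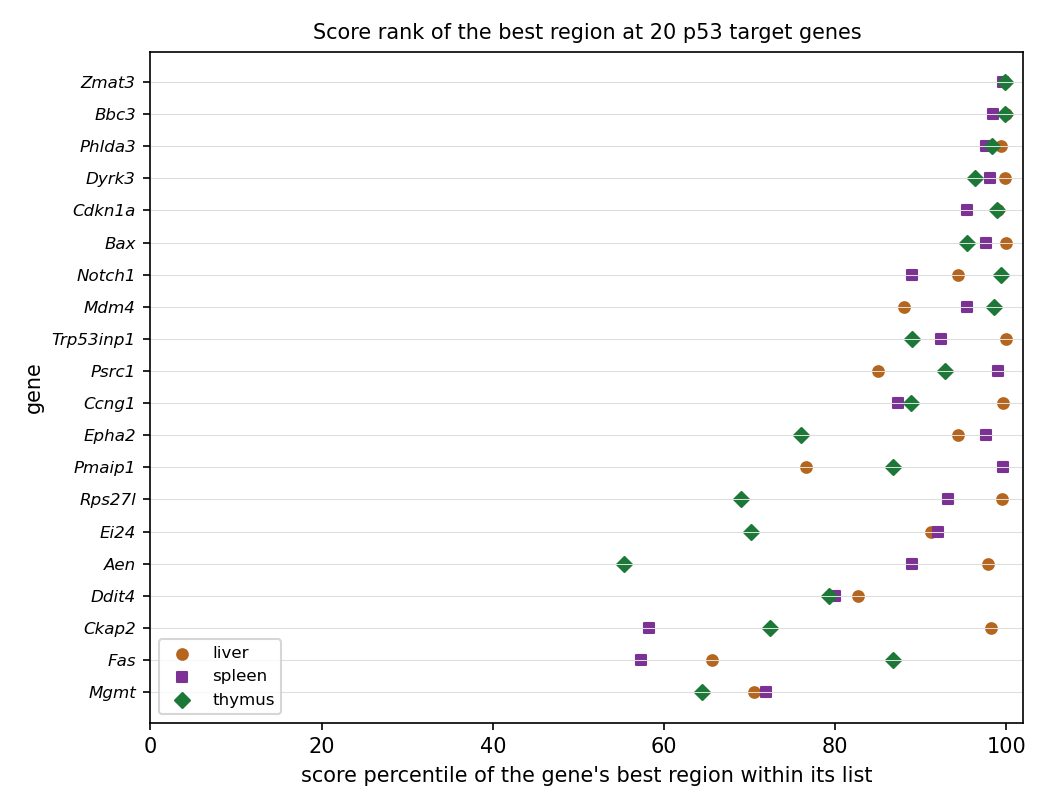
Score percentile (x axis, 0 to 100 within each list) of the best region at 20 p53 target genes (y axis), with circles for liver, squares for spleen and diamonds for thymus. Zmat3 and Bbc3 sit at 98.5 or above in all 3 lists, while Ckap2 ranges from 58.2 in spleen to 98.2 in liver.

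Coverage of the p53 targets was not shown to differ between organs in the main test. Liver and thymus held 49 and 39 of the 85 genes, with 11 genes in liver alone of the pair and 1 in thymus alone (exact McNemar p = 0.00635, adjusted p = 0.324 over 51 tests). With windows of 1 kb around gene ends the same comparison passed, at 36 against 24 genes (adjusted exact p = 0.0249), as it did with 10 kb, at 48 against 37 (adjusted p = 0.0498). The McNemar test takes no account of list length. Of all coding genes, 15.2% had a liver region within 5 kb and 7.17% a thymus region. With windows of 1 kb the random means were 8.33 in liver and 2.26 in thymus, and the ratios to them 4.32 and 10.6. The higher liver counts thus cannot be told apart from the longer liver list. Liver against spleen gave exact p = 0.219 and spleen against thymus p = 0.0313 (adjusted p = 0.797). Best regions of 9 targets in liver, 7 in spleen and 6 in thymus also lay within 5 kb of another coding gene, so the gene they belong to is open. With regions at gene ends removed, 22, 21 and 21 of the 85 genes kept a region (permutation p = 0.0002 in each), and the feedback list no longer passed in any organ (4, 3 and 3 genes; adjusted p = 0.0585, 0.199 and 0.187). Its ratios to the random means were 5.07 (1.497 to 10.1), 4.17 (0.911 to 9.74) and 4.52 (0.987 to 10.5), against 4.21, 7.98 and 7.19 with all regions. This setting was chosen after the data were seen.

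Lists of organ identity did not pass the threshold in any organ. Hepatocyte genes had a region in 1 of 44 cases in liver (random mean 6.63, adjusted permutation p = 0.0514), 1 in spleen and 0 in thymus (adjusted p = 0.548 and 0.241). Without matching on gene length the low liver count passed (adjusted permutation p = 0.041). The region concerned lay 4750 bp outside Ppara, which encodes a regulator of fatty acid oxidation, and also within 5 kb of Cdpf1 and Pkdrej (chromosome 15, 85811601 to 85811750). Genes of lipid, bile acid and xenobiotic metabolism gave 4, 2 and 2 of 30 (random means 5.12, 2.59 and 2.30; adjusted permutation p = 0.972, 1 and 1). Abcb4, the phospholipid transporter of bile, and Lipc, hepatic lipase, each held a region shared by all 3 organs, at 98.4, 90.8 and 98.9 for Abcb4 (chromosome 5, 8921601 to 8921950) and 76.4, 85.0 and 92.0 for Lipc (chromosome 9, 70888101 to 70888350). The lipogenic genes Acly and Fasn had regions in the liver list alone, at percentiles of 33.6 and 5.32. That of Acly lay 3502 bp outside the gene and also within 5 kb of Klhl11. That of Fasn also lay within 5 kb of Ccdc57, so the gene each belongs to is open.

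Immune lists did not pass the threshold either. T-cell genes had a region in 2 of 34 cases in each organ (random means 6.14, 3.53 and 3.13), B-cell genes in 3, 3 and 1 of 29 (5.01, 2.75 and 2.40), and myeloid and erythroid genes in 3, 1 and 1 of 27 (3.46, 1.63 and 1.45). Adjusted permutation p ran from 0.215 to 1 over these lists. The T-cell transcription factor gene Bcl11b held a region at the 85.4 percentile in thymus, 51.8 in liver and 0.0960 in spleen (chromosome 12, 107937601 to 107937850). Tcf12 ranked at 78.7, 96.5 and 91.7, with a different best region in liver. Among B-cell genes, Ciita, the regulator of MHC class II genes, had a region in the spleen list alone (chromosome 16, 10517401 to 10517450; percentile 83.1). Ebf1 had one in spleen and liver (81.9 and 33.7), Bcl11a one in all 3 lists (3.16 in liver, 46.0 in spleen and 38.6 in thymus), and Fcer2a one in liver alone (58.8). Cd68 and Tfrc had regions in liver alone (78.9 and 81.5). The liver regions of Fcer2a and Cd68 lay 3730 and 1463 bp outside these genes. Fcor and Trappc5 also lay within 5 kb of the first, and Eif4a1 and Mpdu1 of the second. Endothelial, stromal and epithelial genes gave 1 of 24 in each organ (Tek; adjusted permutation p = 0.286, 0.900 and 0.972), and NF-kB and interferon genes 2, 1 and 1 of 24 (Bst2 in all 3 and Nfkbia in liver; adjusted p = 0.961, 1 and 1).

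Immediate early, circadian and control lists were also tested. Immediate early genes had a region in 4, 2 and 3 of 22 cases (random means 2.30, 0.954 and 0.842; adjusted permutation p = 0.600, 0.710 and 0.241), with Btg2, Fos, Fosb and Jund in liver. Circadian genes gave 7 of 18 in liver against a random mean of 3.12 (permutation p = 0.0494, adjusted p = 0.139), 4 in spleen and 3 in thymus (adjusted p = 0.309 and 0.600). Nr1d2, which encodes the clock repressor REV-ERB beta, held a region inside the gene that ranked at 98.9, 98.8 and 95.3 (chromosome 14, 18225201 to 18225850). The region 4581 bp from Bhlhe41 ranked at 35.2 in liver against 95.4 in spleen and 97.9 in thymus. Dbp (86.1) and Nr1d1 (63.4) had the next highest circadian percentiles in liver, and Npas2 had regions in all 3 lists. The regions of Dbp and Npas2 also lay within 5 kb of other coding genes. Housekeeping genes gave 8 of 24 in liver (random mean 3.34, permutation p = 0.0236, adjusted p = 0.0708) and 3 in each of spleen and thymus (adjusted p = 0.600 and 0.522). Sdha (91.0), Ppia (74.3), Chmp2a (66.5) and Actb (55.6) led the housekeeping genes in liver. The regions of Sdha and Chmp2a also lay within 5 kb of other coding genes. The neuronal controls gave 2, 1 and 1 of 30 (Mbp in all 3, Syt1 in liver; adjusted permutation p = 0.241, 0.344 and 0.488). Their liver count passed as low with windows of 10 kb (0 genes, adjusted permutation p = 0.0428).

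**Figure D2:**
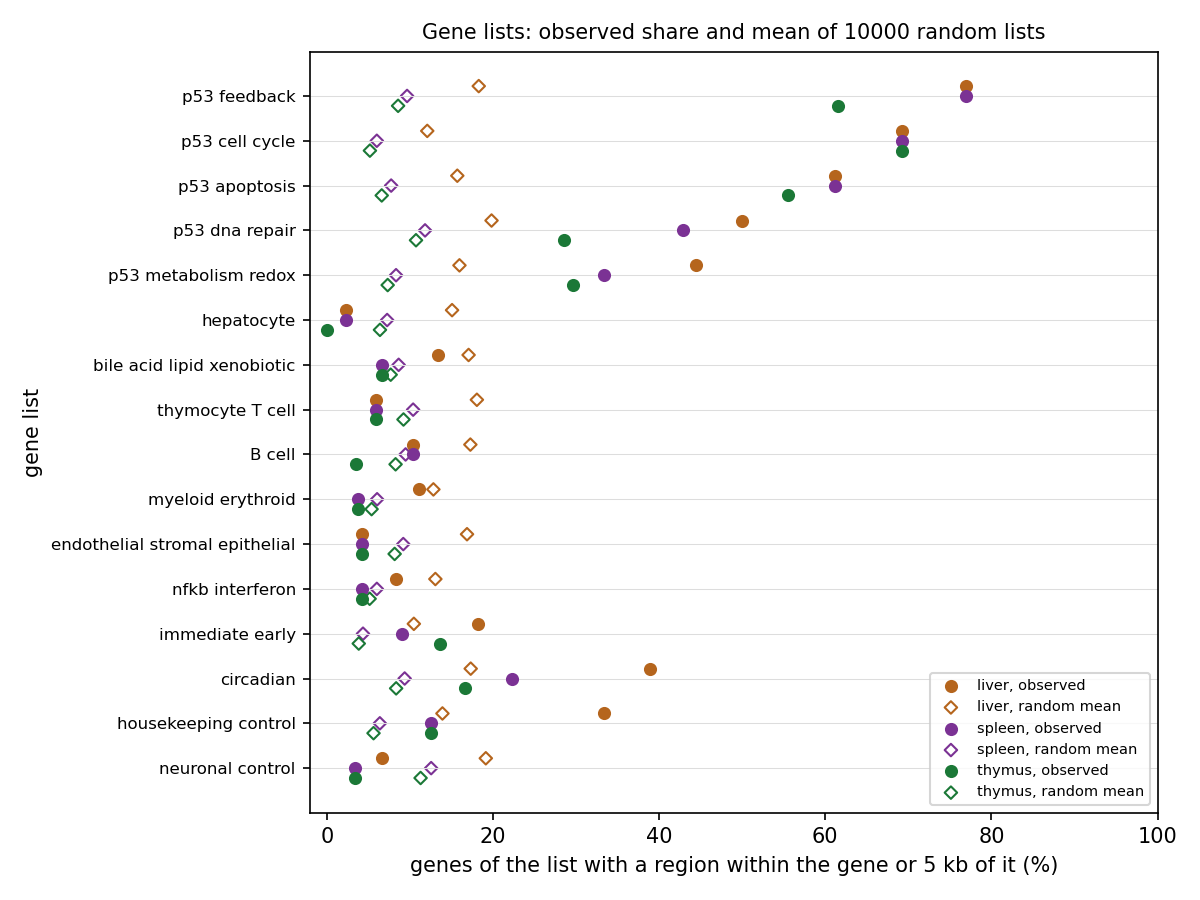
Percent of genes of each fixed list (y axis) with a region inside the gene or within 5 kb (x axis); filled circles are observed shares and open diamonds the means of 10000 random length-matched lists, coloured by organ. The p53 lists lie to the right of their random means, reaching 76.9% for the feedback list in liver and spleen, and the hepatocyte list lies at 2.27% in liver.

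The 3 organs shared most regions of the shorter lists. Spleen regions were found in the liver list in 2368 cases (90.9% of the spleen list, interval 89.8 to 92.0), thymus regions in the liver list in 2179 (90.6% of the thymus list) and thymus regions in the spleen list in 2127 (88.4%). Random placements in the genome shared 1.85, 1.78 and 1.21 regions on average, a contrast that the common region set behind the lists fixes and that says nothing about the organs. Random draws of the same sizes from the 4137 distinct regions would share 93.6% for both liver pairs and 62.9% for spleen and thymus. The liver shares were thus no higher than such draws give, while the 1930 regions in all 3 lists exceed the 1417 that they would give. No test was run on this comparison, because the common set is known only through regions that reached a list. In the upper 50% of each list by score, the share fell to 53.8% for liver and spleen and 52.1% for liver and thymus, against 71.9% for spleen and thymus. With the liver and spleen lists shortened to the 2405 regions of the thymus list, the liver shares were 56.8% and 56.5%, and spleen and thymus shared 85.8%.

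Of the 4137 distinct regions, 1930 (46.7%) were in all 3 lists, 1255 in liver alone, 438 in liver and spleen, 249 in liver and thymus, 197 in spleen and thymus, 39 in spleen alone and 29 in thymus alone. Regions of a single list made up 32.4% of the liver list (30.9 to 33.9), 1.498% of the spleen list (1.07 to 2.04) and 1.21% of the thymus list (0.809 to 1.73). In the upper 50% by score the spleen and thymus counts were 272 and 247, and with equal list lengths 148 and 156. The liver count was 1144 and 853 under these settings, and the count in all 3 lists fell to 535 and 1174.

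**Figure D3:**
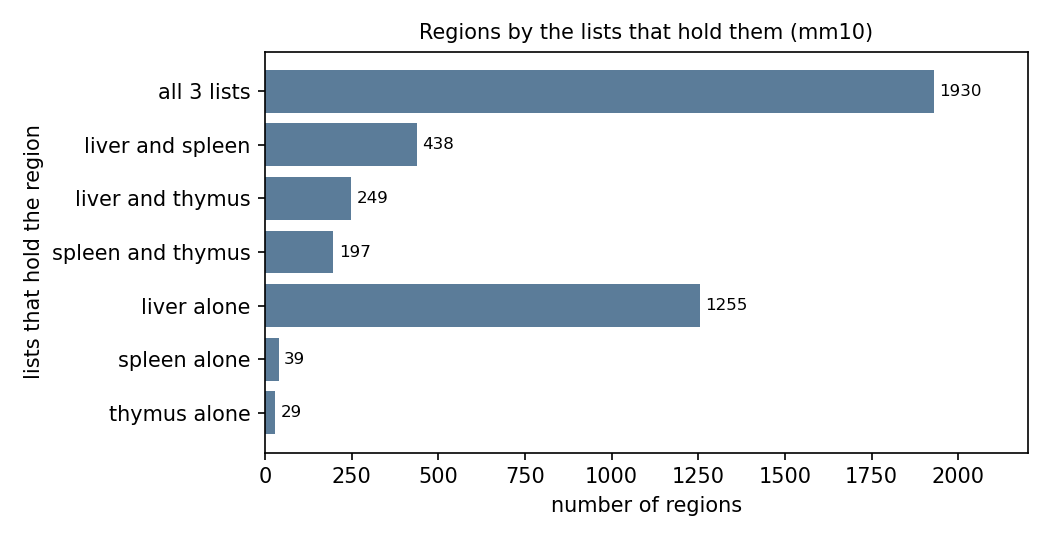
Number of regions (x axis) by the combination of lists that hold them (y axis). The bars for all 3 lists (1930) and for liver alone (1255) are the longest, and those for spleen alone (39) and thymus alone (29) the shortest.

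Liver regions lay at gene ends far more often than those of the lymphoid organs. Within 1 kb of a gene end were 47.6% of liver regions (46.0 to 49.2), 25.5% of spleen regions (23.9 to 27.3) and 23.6% of thymus regions (21.9 to 25.4), against 6.33%, 6.27% and 6.26% in random placements of the same regions (n = 3872, 2604 and 2405; p = 0.002 each). Liver differed from spleen (odds ratio 2.65, adjusted p = 6.71e-73) and from thymus (odds ratio 2.94, adjusted p = 1.1e-82) by Fisher's exact test, while spleen against thymus gave p = 0.115. These tests treat the lists as independent, although most regions of the shorter list count on both sides. Among regions that only 1 list of a pair holds, an alternative chosen after the data were seen, the shares were 79.7% in liver and 8.05% in spleen, and 76.5% in liver and 8.41% in thymus (Fisher's exact adjusted p = 1.7e-104 and 1.29e-91). For spleen and thymus the order turned, at 59.7% of 477 regions and 67.6% of 278 (Fisher's exact adjusted p = 0.0352). A further 28.9%, 39.0% and 39.8% lay inside genes away from their ends, and 23.5%, 35.5% and 36.5% outside genes.

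Regions in the liver list alone were mostly at gene ends. The share among them was 80.9% (78.6 to 83.0), against 19.0% of regions in all 3 lists (17.2 to 20.8; odds ratio 18.1, Fisher's exact adjusted p = 2.07e-274). Regions that liver shared with 1 other organ were also often at gene ends, at 63.9% with spleen and 73.5% with thymus. By contrast the share was 7.11% (3.94 to 11.6) for regions in spleen and thymus without liver, below that of regions in all 3 lists (Fisher's exact adjusted p = 1.04e-05). Regions of 50 bp made up 35.2% of liver-alone regions and 13.9% of those in all 3 lists (Fisher's exact adjusted p = 6.72e-44). The p53 targets were not enriched among liver-alone regions (8 of 85 genes, random mean 6.50, permutation p = 0.643), whereas regions in all 3 lists covered 38 (random mean 4.86, p = 0.0002).

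**Figure D4:**
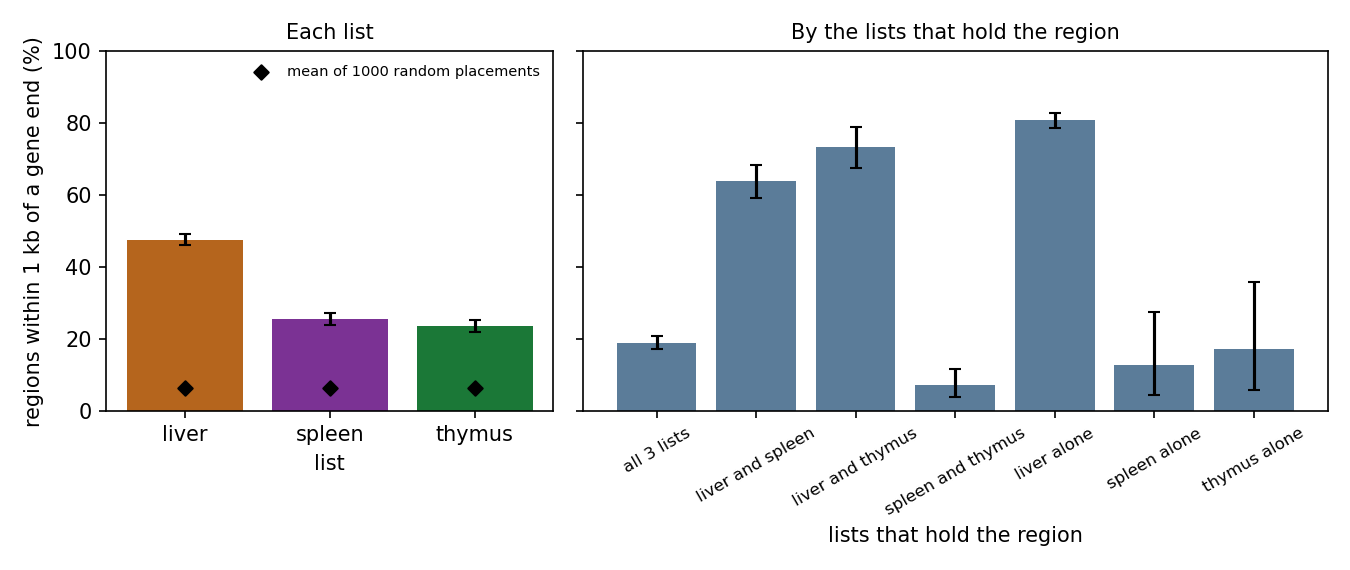
Percent of regions whose midpoint lies within 1 kb of a gene end (y axis), for each list (left) and by the lists that hold the region (right); error bars are exact 95% intervals and black diamonds the means of 1000 random placements. Liver-alone regions stand at 80.9% and regions in all 3 lists at 19.0%.

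The gene-end share varied with the score in spleen and thymus, a trend described here and not tested. In spleen it was 63.5% among the 20% of regions with the lowest scores and 11.2% among the 20% with the highest, and in thymus 52.5% and 11.6%. In liver the 5 score classes, from lowest to highest, gave 39.1%, 50.3%, 50.7%, 53.05% and 45.0%. In the upper 50% by score, the spleen and thymus shares at gene ends were 12.7% and 12.3% against 49.1% in liver. Regions held by liver and spleen without thymus had a median spleen percentile of 15.1, and those held by liver and thymus without spleen a median thymus percentile of 14.1.

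**Figure D5:**
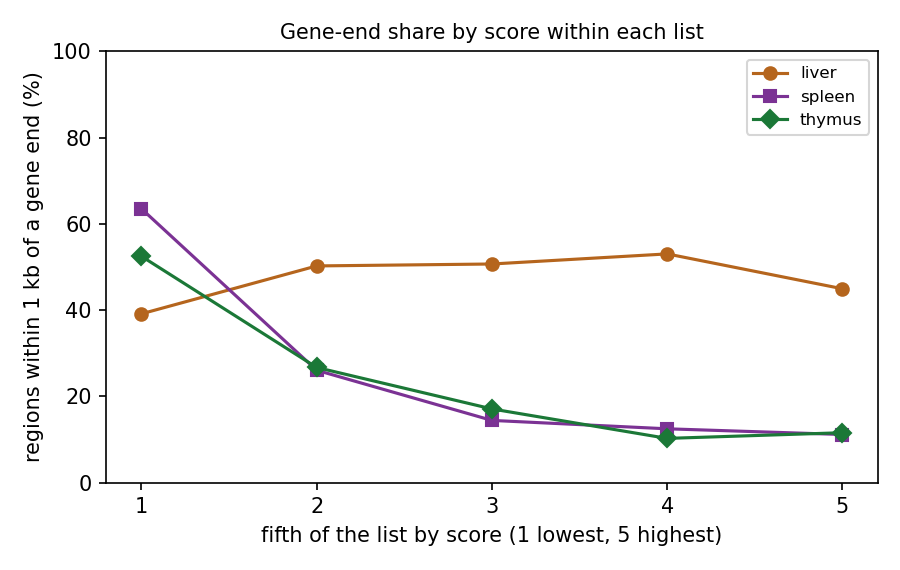
Percent of regions within 1 kb of a gene end (y axis) in 5 score classes of each list, from lowest to highest (x axis), with circles for liver, squares for spleen and diamonds for thymus. Spleen drops from 63.5% to 11.2% and thymus from 52.5% to 11.6%, while liver stays between 39.1% and 53.05%.

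Score ranks of shared regions correlated more closely between spleen and thymus than between either of them and liver. Spearman's rho across regions was 0.54 for spleen and thymus (bootstrap interval 0.51 to 0.57), 0.17 for liver and spleen (0.12 to 0.21) and 0.18 for liver and thymus (0.14 to 0.22). Regions shared with another list had median percentiles of 51.2 in liver, 50.1 in spleen and 50.2 in thymus, against 48.4, 46.5 and 41.8 for regions of that list alone. None of these score differences passed the permutation test (adjusted p = 0.294, 0.661 and 0.539). In spleen and thymus that test had only 39 and 29 single-list regions. The share of regions held by all 3 lists rose with score in spleen, from 42.6% in the lowest score class to 93.1% in the highest. In thymus it rose from 58.1% to 94.4%. Liver showed no steady rise, at 50.8% in the lowest class, 45.4% in the class below the highest and 61.1% in the highest. These shares were not tested. Shared regions were wider: ranked by width in place of score, they lay 26.8, 50.2 and 50.2 percentile points above single-list regions (adjusted permutation p = 6e-05, 6e-05 and 0.00015).

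The highest-scoring regions of each organ were all shared by the 3 lists. In liver the 10 highest had as nearest coding genes Bbc3, Mtmr10, Ier5, Trp53inp1, Bax, Dyrk3, Mdm2, Yipf5, Zmat3 and Abca8b, 6 of them in the p53 lists. The high-scoring region assigned to Mdm2, the ubiquitin ligase that degrades p53, lay 6643 bp outside the gene (chromosome 10, 117717401 to 117717950). Mdm2 also had a region across its gene end in all 3 lists (117709901 to 117710950). That region ranked lower, at percentiles of 76.0 in liver, 63.5 in spleen and 27.0 in thymus. In spleen the nearest genes were Elmo1, Mgat5, Tmigd1, Arpin, Txlnb, Zmym5, Zc3hav1, Abca8b and Scp2, and the remaining region, on chromosome 19 (32912801 to 32913450), had no coding gene within 50 kb. In thymus they were Bbc3, Mrps31, Pkd2l1, Slc25a36, Dnm3, Zmat3, Map3k7, Sergef, Gm42048 and Elmo1. Of these, 0 in spleen and 2 in thymus were in the p53 lists. The Elmo1 region, inside a gene for a Rac activator (chromosome 13, 20135001 to 20135850), was thus among the 10 highest in spleen and thymus. Tied scores decided part of these orders, with 7 spleen and 9 thymus regions at the highest score. The best spleen regions of Zmat3 and Pmaip1 (percentile 99.6 each) had the same score as the Abca8b, Scp2 and chromosome 19 regions. Only the tie order left them out of the 10, so the spleen count of 0 rests on that order.

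Regions over 10 kb from both other lists numbered 1165 in liver, 33 in spleen and 26 in thymus. The highest in liver had no coding gene within 50 kb (chromosome 12, 27941201 to 27941750; percentile 96.9). It was followed by a region 2396 bp outside Serpina3n, an acute-phase serine protease inhibitor gene (chromosome 12, 104404001 to 104404250; 96.7), and by regions whose nearest coding genes were Bbs2, Adamts4, Naxe, Fxyd1, Unc5cl, Slc38a2 (9873 bp away) and Zfp324, with another on chromosome 1 (35663001 to 35663250) away from coding genes. In spleen the nearest coding genes were Bmt2 (92.0), Coq5 (87.3), Ciita (83.1), Gm32742, Gpam, Adgrl2, Clasp2 and Tnfsf18, beside 2 regions with no coding gene within 50 kb. In thymus they were Dtl (22306 bp away; 91.3), Pde4d (73.3), Trappc9, Nudcd3, Txnrd2, P3h4 and Myh9, beside 3 regions with no coding gene within 50 kb. One of these 3 lay in the T-cell receptor alpha locus, Tcra (chromosome 14, 53794601 to 53794650; 81.2).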

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

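The tests of weak regions, of narrow regions, of hepatocyte and liver metabolism genes, of regions that only 1 list of a pair holds and of regions in all 3 lists away from gene ends in this part were chosen only after the results they bear on had been seen. The share of regions within 1 kb of a gene end differed between organs by a direct test: it was 47.6% in liver against 25.5% in spleen and against 23.6% in thymus. Liver also led among regions that only 1 list of the pair holds (79.7% against 8.05%, and 76.5% against 8.41%). Each contrast compares 1 list with 1 list, so organ, read depth and any difference in how the lists were made are confounded.

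Regions in the liver list alone lay at gene ends in 80.9% of cases. The tables argue against regions that are weak within liver, since their median liver percentile was 48.4. That rank cannot tell whether they fell just under the minimum in spleen and thymus, so this stays open. Regions shared with spleen alone had a median spleen percentile of 15.1, and those shared with thymus alone a median thymus percentile of 14.1. Moving each region by 50 to 500 kb left 10.3% at gene ends on average and at most 13.1% over 1000 sets of moves. The share thus exceeds what random positions in the same surroundings would give. Windows of 1 kb around gene ends cover little of any surroundings, so the moves could hardly reach 80.9%. They therefore cannot decide on gene-rich surroundings as a cause, which stays open. Narrow regions of 50 bp made up 35.2% of these regions against 13.9% of those in all 3 lists, and shared liver regions ranked 26.8 percentile points higher by width, yet such regions are argued against as the whole cause, since 82.0% of the wider liver-alone regions lay at gene ends against 19.5% of the wider ones in all 3 lists. Counts were too few to decide on background at the ends of broadly used genes (2 housekeeping genes with a liver-alone region at a gene end, random mean 1.51) or on binding at hepatocyte identity and liver metabolism genes (2 of 73 genes with a liver-alone region, random mean 5.74, permutation p = 0.135). Also open and untested are read depth and organ differences in open chromatin, because no values were analysed here for regions absent from a list.

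Score order in liver differed from that in spleen and thymus, with rho of 0.17 and 0.18 against 0.54. Gene-end regions that rank high in liver are argued against as the whole cause, since over shared regions away from gene ends rho between liver and spleen was 0.27 (0.22 to 0.31), still below the 0.48 (0.44 to 0.51) of spleen and thymus. Over regions of all 3 lists away from gene ends it rose to 0.32 (0.27 to 0.37), past the bound of 0.3 set in advance for the first value yet below the 0.52 (0.47 to 0.55) of spleen and thymus, so gene-end regions as part of the cause stay open. Repeated score values at the top of the lists are argued against too, because rho over regions with unique scores was 0.0323 for liver and spleen (-0.05 to 0.11) and 0.41 for spleen and thymus. A real difference between organs stays among the open explanations and was not tested, since a single list per organ gives no measure of how far rho would vary between replicates of 1 organ.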

How the results depend on the processing

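Settings limited to regions away from gene ends, to regions in all 3 lists, to both together, to unique scores, to regions that only 1 list of a pair holds and to regions wider than 50 bp, and draws from the distinct regions, were chosen after seeing the data. No paired analysis was possible because no values per library were analysed here; leaving out replicates, the radiation test and the motif alternatives were not run for the same reason or for lack of a sequence. The gene-end shares of whole lists, set against random placements, kept their direction and their side of the threshold under every alternative run for them, at 12.3% to 64.7%. So did the combined p53 counts against random lists. Overlaps ranged from 52.1% to 91.0%, and that all stayed above random carries no information: reciprocal overlap and midpoint distance could not change them, as shared regions have identical boundaries, and the placements ignore the common region set. Against draws from the distinct regions the liver overlaps turned to below the expected counts (90.9%, 2368 against 2437, with spleen, and 90.6%, 2179 against 2251, with thymus). Regions that reached no list are missing from these draws, and each region absent from liver must be in spleen or thymus. This lowers the liver overlaps by construction. In the upper 50% by score, regions in all 3 lists numbered 535, spleen alone 272 and thymus alone 247; at equal list lengths, 1174, 148 and 156. Shorter lists lower the first count by construction. A region became newly single only where its matches were cut from the other lists, so the other counts rose through the shortening too. At equal list lengths the thymus list itself was not cut. What sets the size of these rises was not tested. Width in place of score made the difference of shared from single regions pass, at 26.8 (liver), 50.2 (spleen) and 50.2 (thymus) percentile points. Wider than 50 bp, the contrast of liver alone with all 3 lists stayed (odds ratio 18.9), as did those of liver with spleen (2.30) and thymus (2.80), and spleen exceeded thymus at gene ends (odds ratio 1.22, Fisher's exact p = 0.00781 adjusted over 4 comparisons), whereas among regions that only 1 of the lists holds the order turned (odds ratio 0.711, adjusted p = 0.0352). Away from gene ends, 3 lists passed in spleen in place of 5, and 10 of the 20 named p53 targets had a region in all 3 lists. A difference between organs appeared in 1 comparison with windows of 1 kb and 1 with 10 kb, both the combined p53 list in liver against thymus. That test takes no account of the longer liver list. The rank correlation of scores, as Spearman's rho, moved to 0.27, 0.26 and 0.48 away from gene ends (liver and spleen, liver and thymus, spleen and thymus), to 0.0323, 0.0334 and 0.41 with unique scores, to 0.26, 0.20 and 0.58 in regions of all 3 lists, and to 0.32, 0.29 and 0.52 with both limits. Of 336 values for single gene lists under alternatives, 284 kept direction and side of the threshold, 8 lost the call and 4 gained one; 40 turned direction relative to the random mean, none of them past the threshold in either setting, at counts of 0, 1, 2, 3, 4 or 5 genes. The causes of these were not tested. Read depth is unknown and limits what absence from a list means.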

Other observations

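The tests of gene families in this part were chosen only after the data were seen. Regions of the liver list alone lay inside or within 5 kb of 5 of 18 listed circadian genes, Dbp, Per1, Nr1d1, Nr1d2 and Tef, against a random mean of 1.46 (permutation p = 0.0248, adjusted p = 0.446 over 18 lists). The count therefore failed the correction. Nr1d1 and Nr1d2 encode the REV-ERB clock repressors, and Dbp and Tef encode PAR bZIP transcription factors that drive rhythmic liver genes. Away from gene ends, a setting chosen after the data were seen, the circadian list passed in the whole liver list. It had 5 genes against a random mean of 1.06 (adjusted permutation p = 0.0326, against 0.139 with all regions). Npas2, Bhlhe41 and Nr1d2 had such regions in all 3 lists and Dbp in liver and spleen, so these members are not particular to liver. The same liver-alone regions included none at the 44 hepatocyte markers (random mean 3.34, permutation p = 0.0694) and none at the 34 T-cell markers (random mean 2.74, p = 0.112).

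Families of coding genes that share a symbol stem were counted among liver-alone regions, 153 families in all. Olfactory receptors (Olfr) had 0 of 1110 genes near a liver-alone region against a random mean of 17.8, and vomeronasal receptors (Vmn) 0 of 355 against 14.1 (adjusted permutation p = 0.0153 for each). Members of these families lie in clusters, so their genes are not independent. Cytochrome P450 genes (Cyp), which include the drug-metabolising enzymes of liver, had 1 of 99 against 8.12 (adjusted permutation p = 0.176), and ATPase genes (Atp) had 15 of 85 against 6.53 (adjusted p = 0.176). The families next by p lay above their random means. They were Eif (11 against 4.40), Ap (8 against 2.47), Rpl (8 against 2.64), Kdm (6 against 1.63), Ube (9 against 3.45) and Usp (11 against 4.74). Their adjusted permutation p ran from 0.18 to 0.187. Slc, which followed, lay below (19 against 31.5, adjusted permutation p = 0.231). Among regions in all 3 lists no family passed. The lowest p there was that of the vomeronasal receptors, with 1 of 355 genes against 8.88 (permutation p = 0.002, adjusted p = 0.306).

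Of the genes in the p53 lists, 35 had no region within 5 kb in any list. Gadd45a, Xpc, Perp, Tigar, Sfn, Rrm2b, Ddb2 and Gls2 were among these 35 genes, named after their values were seen. A region of the liver list alone lay inside Trp53 itself or within 5 kb of it (chromosome 11, 69584801 to 69584950, percentile 48.4). It lay 4551 bp from Wrap53 and is the best liver region for Wrap53. Another near Trp53, across the end of Wrap53, was in all 3 lists (69580201 to 69580350). Sesn1 had its region, at the 85.3 percentile, in the liver list alone (chromosome 10, 41809801 to 41810050), whereas Sesn2 had one in liver and spleen. The Sesn1 region lay 524 bp outside the gene and also within 5 kb of Cep57l1.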
